A study of Mus musculus with 4 samples.

How the data were processed

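Guide abundance was measured in 4 libraries of a pooled CRISPR-Cas9 knockout screen, 2 from sorted MERVL-positive cells and 2 from total cells. Per the labels, the library held 130209 guides against 20611 genes. About 130000000 embryonic stem cells were transduced for 24 h with 4 ug/mL polybrene and selected for 48 h with 2 ug/mL puromycin, and about 500000 reporter-positive cells were sorted at day 5. These numbers come to 998 transduced cells and 3.84 sorted cells per library guide. Genomic DNA was extracted, and guide sequences were amplified by PCR, per the labels' protocols.

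The values came from 1 table made by the authors, in which each of 22510 entries has 1 comparison between the groups and no value per library. The authors' deposited table has the column names of a MAGeCK gene summary, per the file headers, and the submitters' processing notes name MAGeCK and the mm10 genome build. The version, the settings, the normalization and the group taken as treatment are not given in the sources used here. For each entry and each direction of change, the authors deposited a score, per the file headers. It is taken here as the robust rank aggregation score of MAGeCK, smaller for stronger entries, which the headers do not state. A p-value and a false discovery rate per entry and direction were deposited beside the score. The authors also deposited a log2 fold change between the groups, with identical values in its 2 columns. Other deposited columns are the number of guides per entry, the rank, and the number of guides past a guide threshold in each direction, called guides up and guides down here. In the 1112 entries with 1 guide, this threshold fell at a score of 37.35% to 37.48% for positive change. For negative change it fell at 37.87% to 37.96%. The threshold is thus loose, with 37.4% of guides up and 38.0% down over all genes, and a guide past it need not have changed. How the guide values were combined into the gene log2 fold change is not given in the sources used here. The deposited false discovery rates differed from a Benjamini-Hochberg adjustment of the deposited p-values by at most 2.88e-05 in the positive and 4.35e-05 in the negative direction.

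The design written before the data were examined foresaw both guide counts per library and a table of gene values. The table of gene values applied, so no count model was fitted, and the authors' p-values and false discovery rates were taken as deposited, with a threshold of 0.05. Depth per library is unknown, and no library could be compared with its repeat. The titles call the libraries sequencing repeats and name no separate cultures. The deposited p-values may therefore rest on technical spread alone.

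The entries were split by name into 20380 genes, 1132 microRNAs and 998 single non-targeting control guides. They hold 121918 guides, 93.6% of the library's number, and the remaining guides were not analysed here. Gene names and positions came from a RefSeq table of the GRCm38.p6 assembly, which has the coordinates of mm10. Of the genes, 19061 matched by symbol, 1212 by synonym and 107 not at all.

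Before the data were examined, 33 gene lists were fixed, covering the Integrator complex, other transcription and chromatin complexes, regulators of the 2-cell state, pathways, essential complexes and 3 receptor and keratin families usually silent in embryonic stem cells, whose expression was not measured here. Of their members, 2185 were in the table and 5 were missing. The median gene log2 fold change of each list was set against 100000 random lists of the same size, matched on guides per gene, in a two-sided permutation test with Benjamini-Hochberg adjustment over the 33 lists. The smallest p this test can give is 1e-05. Genes and guides are not replicates, so this test and the binomial tests of guide shares describe these libraries. Deposited p-values of list members were also adjusted over the list alone, which takes no account of the number of lists. Simulated lists, 50 per setting, were drawn from those of the 20380 genes with 5 or 6 guides and set against fewer random lists. On these the test found 84% of 14-gene lists and 100% of 79-gene lists shifted by -0.4 at an unadjusted p under 0.05. For a shift of -0.2 it found 14% and 98%, and with no shift 6% of both.

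Genes were named by a rule fixed before the data were examined. It took the 15 genes with the best enrichment p, the 5 with the best depletion p, and all Integrator subunits. From each fixed list it took the members past the threshold or, where there were none, the best-ranked member for enrichment if its unadjusted p was under 0.05. The rule named 52 genes, and any other gene in the text was chosen after its values were seen. Also chosen after the values were seen were 16 further gene lists, medians over 21 chromosomes, 66 exact binomial tests of guide shares, 5 differences between lists, the tests of receptor counts, the spread and concordance of guides, the comparison of receptor genes with control guides, and the test of direction. A first pass of the list test with fewer random lists preceded the final one. The alternatives tried were other thresholds, a minimum number of guides, a minimum fold change, other statistics and backgrounds for the lists, and the opposite reading of direction. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.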

Results

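The screen used E14, an established line of mouse embryonic stem cells, carrying a tdTomato reporter of MERVL. MERVL is an endogenous retrovirus that is active in the 2-cell embryo and in a rare 2-cell-like state of cultured embryonic stem cells. A pooled lentiviral library of CRISPR-Cas9 guides knocked out genes across the genome, and reporter-positive cells were sorted from it at day 5. The 4 libraries comprise 2 of MERVL-positive cells and 2 of total cells, called sequencing repeats in their titles. The values analysed are the authors' comparison of the groups, with 1 log2 fold change per gene and no value per library, so depth per library is unknown and no gene has a spread between libraries. The authors' deposited table covers 20380 genes, of which 79.8% have 6 guides, together with 1132 microRNAs and 998 single non-targeting guides. The comparison asks which knockouts switch MERVL on, and the study's title names the Integrator subunit Ints7.

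The authors' deposited table does not state which group is the numerator. A positive log2 fold change is read here as more guides in MERVL-positive cells, which is likely but not settled. Its basis is the title, which ties loss of Ints7 to active MERVL, together with the place of Ints7 at rank 157 of 22510 for positive and 18586 for negative change. This basis uses the study's own result, so the sign of Ints7 is not independent evidence of the direction. With the opposite reading, every direction below turns.

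Guides against ribosomal protein genes fell in MERVL-positive cells, with a median log2 fold change of -0.45 over 79 genes. Guides against genes of DNA replication and its ATR-CHK1 checkpoint fell as a group of 48, with a median of -0.27, a call that was lost when ranks took the place of fold changes. The 1093 olfactory receptor genes, usually silent in these cells, had a median of 0.031, above the -0.021 of all genes. The median of single non-targeting guides was close, at 0.019. In the authors' deposited table, 1 single gene passed a false discovery rate of 0.05, the predicted gene Gm10413, which fell by 0.99 on the log2 scale. No gene passed for enrichment in the authors' deposited table, where the lowest false discovery rate was 0.827. With about 3.84 sorted cells per library guide, the lack of a call does not show that a knockout had no effect.

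Ints7 is a subunit of Integrator, the complex that cleaves nascent transcripts of RNA polymerase II and ends transcription at snRNA and other genes. It lies on chromosome 1 from 191575540 to 191623690 in mm10. In the authors' deposited table it had a log2 fold change of 0.14, a ratio of 1.11, with 3 of 6 guides up and 1 down. Its enrichment p in the authors' deposited table was 0.00714, with a false discovery rate of 0.931. Ranked by log2 fold change instead of p, it stood at 7877 in the authors' deposited table.

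Ints1, the scaffold-like largest subunit, on chromosome 5 from 139751282 to 139775702, had a log2 fold change of 1.37 in the authors' deposited table, with 6 of 6 guides up, rank 194 and an enrichment p of 0.00887 at a false discovery rate of 0.949. Of the 14 subunits, 10 had a log2 fold change above 0 and 2, Ints7 and Ints1, had an unadjusted enrichment p under 0.05 in the authors' deposited table. Ints9, the partner of the catalytic subunit, and Ints4, which joins both in the cleavage module, had values of 0.54 and 0.54 in the authors' deposited table, each with 4 guides up and none down. The catalytic subunit Ints11, listed as Cpsf3l, had a value of -0.16 in the authors' deposited table, and Ints2 had the lowest value, -0.54. The other subunits were Ints8 at 0.47, Ints12 at 0.46, Ints14 at 0.42, Ints10 at 0.25, Ints13 at 0.22, Ints6 at 0.051, Ints5 at -0.032 and Ints3 at -0.37 in the authors' deposited table.

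The median of the Integrator subunits was 0.23, inside the -0.30 to 0.24 that held 95% of random lists (two-sided permutation p = 0.0705, adjusted p = 0.291 over 33 lists). No subunit passed when deposited p-values were adjusted over the list alone, where the lowest value was 0.0621. Of the 80 guides against the 14 subunits, 42 were up in the authors' deposited table, which is 52.5% (exact 95% interval 41.0 to 63.8) against 37.4% of guides over all genes. In an exact binomial test chosen after the values were seen, p was 0.00744 and the adjusted p over 66 such tests was 0.0702. Without Ints7, the subunit that the title names, the median was 0.25 (permutation p = 0.0703). The permutation p was 0.0262 for the mean of the 14 subunits, 0.00994 for their median enrichment rank and 0.0772 for their median depletion rank, with adjusted p-values of 0.168, 0.082 and 0.425 over 33 lists. Without Ints7 these permutation p-values were 0.0273, 0.032 and 0.124.

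**Figure D1:**
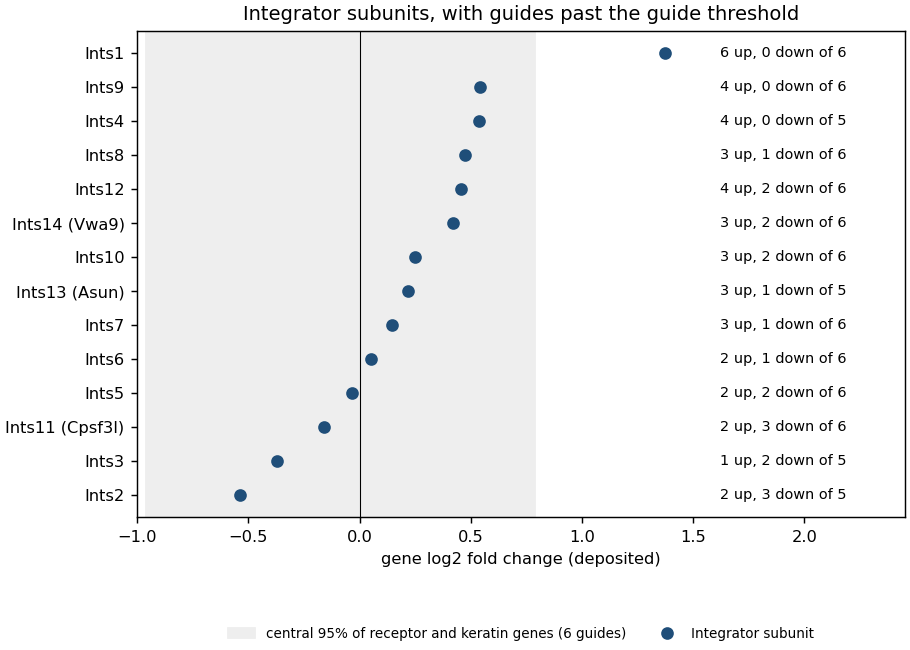
Log2 fold change of each of the 14 Integrator subunits in the authors' deposited table (horizontal axis), with its guides up and down. The grey band is the central 95% of receptor and keratin genes with 6 guides, -0.96 to 0.79, and Ints1 at 1.37 is the subunit outside it.

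The 15 genes ranked first for enrichment had log2 fold changes from -0.32 to 2.00 in the authors' deposited table, all with a false discovery rate of 0.827. They include Slirp, which stabilises mitochondrial mRNA (log2 fold change 0.72, chromosome 12 from 87443896 to 87449924), and Dcps, a scavenger of mRNA caps (0.75, chromosome 9 from 35124414 to 35175987), in the authors' deposited table. Dmap1, a subunit of the TIP60 and SRCAP chromatin complexes (1.00, chromosome 4 from 117674681 to 117682321), and Tcf7l2, a transcription factor of the Wnt pathway (1.14, chromosome 19 from 55741797 to 55933659), were also among them in the authors' deposited table. All guides of these 4 genes, and of Mcpt8 and the olfactory receptor gene Olfr494, were up in the authors' deposited table. The heat shock factor gene Hsf3 had a value of 1.63 and the predicted gene Gm5592 a value of 2.00 in the authors' deposited table, each with 4 of 5 guides up. Proser2, ranked first, had 4 of 6 guides up and a log2 fold change of 0.33 in the authors' deposited table. The remaining entries of this group were Rbm28, Fam122a, the microRNA mmu-mir-92a-2, and the olfactory receptor genes Olfr1097, Olfr965 and Olfr898 in the authors' deposited table. Among these 15, 4 were olfactory receptor genes. Olfr1097, at rank 4 for enrichment, had a log2 fold change of -0.32 in the authors' deposited table, with 2 guides up and 3 down.

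For depletion, Gm10413 on chromosome 14 from 3395093 to 3403534 had a p of 2.2e-07 and a false discovery rate of 0.00495 in the authors' deposited table. Of its 4 guides, 3 were down and 1 was up in the authors' deposited table. Guides for a predicted gene can match related copies elsewhere, and the guide sequences were not used here, so its value is uncertain. Tomm40, the channel of the outer mitochondrial membrane import complex, came next in the authors' deposited table, with a log2 fold change of -0.77 and a false discovery rate of 0.27. Of its 6 guides, 3 were up and 3 down in the authors' deposited table. After Tomm40 came Gpr6 at -1.55, Olfr645 at -1.51 and Nckipsd at -0.45 in the authors' deposited table, with false discovery rates of 0.282, 0.462 and 0.482. Their guides up and down in the authors' deposited table were 2 and 4, 1 and 3, and 2 and 3, in that order. Gpr6 also had an unadjusted enrichment p of 0.0369 in the authors' deposited table.

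Over all genes, 1023 had an unadjusted enrichment p under 0.05 and 1034 an unadjusted depletion p under 0.05 in the authors' deposited table, where uniform p-values would give 1019. At 0.001 the authors' deposited table had 19 and 28 genes, where 20.38 would be given. Among the non-targeting guides 39 and 56 passed 0.05 in the authors' deposited table, against 49.9. At stricter thresholds more of them passed for depletion than for enrichment in the authors' deposited table, with 18 and 6 at 0.01 against 9.98, and 3 and 0 at 0.001 against 0.998. A common movement of the guides of 1 gene was not detected, and at 3.84 sorted cells per library guide it is not excluded. In the 16270 genes with 6 guides, the variance of the number of guides up was 0.992 times the binomial variance (bootstrap 95% interval 0.973 to 1.01), and that of guides down was 1.02 times (0.995 to 1.04). All 6 guides were up in 35 of these genes in the authors' deposited table, and 44.4 would be given by independent guides, while all 6 were down in 59, against 49.2. Among these, the 62 ribosomal protein genes had 56.2% of guides down. All 6 guides were down in 3 of the 62, against 0.188 at the share of all genes. Their variance of guides down was 1.07 times the binomial variance (bootstrap 95% interval 0.719 to 1.42).

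**Figure D2:**
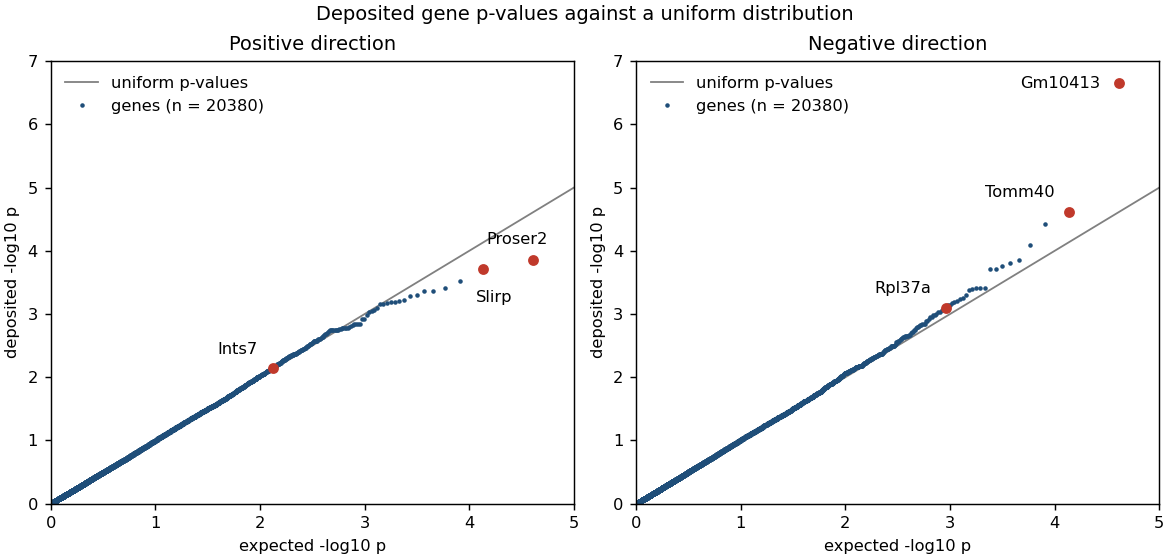
Enrichment (left) and depletion (right) p-values of the 20380 genes in the authors' deposited table, as -log10 p against the -log10 p of a uniform distribution, with the line of equality. Enrichment p-values follow the line at Ints7 and lie below it at the first ranks, where Proser2 has 0.000141, while Gm10413 at 2.2e-07 lies above it for depletion.

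Ribosomal protein genes, most of which encode the cytosolic ribosome, had a median outside the -0.14 to 0.093 that held 95% of random lists. The permutation p was 1e-05, the smallest this test can give, and the adjusted p over 33 lists was 0.00033. Of the 79 genes, 67 had a log2 fold change below 0, and 11 had an unadjusted depletion p under 0.05 against 3.95 by chance in the authors' deposited table. The 11 include the like-named genes Rpl7l1 and Rpl10l, the second with 6 of 6 guides down in the authors' deposited table. No ribosomal protein gene had an enrichment p under 0.05 or passed a false discovery rate of 0.05 in the authors' deposited table, and none passed adjusted over the list alone (lowest value 0.0624). Chosen after their values were seen, Rpl37a had a log2 fold change of -2.51 and Rpl12 one of -0.89 in the authors' deposited table, each with 6 of 6 guides down. Of the 451 guides against these genes, 55.4% were down and 23.7% up in the authors' deposited table, against 38.0% and 37.4% over all genes.

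The list of DNA replication and ATR-CHK1 genes had a permutation p of 0.00098 and an adjusted p of 0.0132, with 35 of 48 genes below 0. Among 6 genes with an unadjusted depletion p under 0.05 in the authors' deposited table were Cdc45 at -1.20, a part of the replicative helicase, and the origin recognition subunit Orc4 at -0.92, both chosen after their values were seen. Chek1, the checkpoint kinase, had a value of 0.57 and an unadjusted enrichment p of 0.0262 in the authors' deposited table. No member passed adjusted over the list alone, where the lowest value was 0.104. The group's call was lost with ranks in place of fold changes, at an adjusted permutation p of 0.903 for the enrichment rank and 0.127 for the depletion rank. Of its 280 guides, 45.4% were down and 30.4% up in the authors' deposited table, with adjusted exact binomial p-values of 0.0952 and 0.105 over 66 tests.

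Other complexes needed by dividing cells did not pass by their medians. The median was 0.014 for 48 spliceosome genes, -0.087 for 39 proteasome genes, -0.062 for 76 mitochondrial ribosomal protein genes and -0.17 for 47 genes of RNA polymerase I and rRNA processing, with adjusted permutation p-values of 0.802, 0.693, 0.752 and 0.275. Of the 271 guides of the RNA polymerase I list, 47.2% were down and 28.4% up in the authors' deposited table, which passed 0.05 in exact binomial tests chosen after the values were seen (adjusted p = 0.0231 for each over 66 tests). Its mean and median enrichment rank had adjusted permutation p-values of 0.0622 and 0.0598. The binomial tests count guides as independent, and guides are not replicates. Ribosomal protein genes lay below the spliceosome genes by a median difference of -0.46 (95% interval -0.65 to -0.28, permutation p = 1e-05, the smallest possible, adjusted p = 2.5e-05 over 5 differences). Against the mitochondrial ribosomal protein genes the difference was -0.39 (-0.57 to -0.21, the same p and adjusted p), and against the proteasome genes -0.36 (-0.56 to -0.047, permutation p = 0.00189, adjusted p = 0.00315). Against the replication list it was -0.17 (-0.42 to -0.0082, permutation p = 0.0499, adjusted p = 0.0499), and against RNA polymerase I -0.28 (-0.48 to 0.003, permutation p = 0.00831, adjusted p = 0.0104). For the last of these the bootstrap interval holds 0 while the permutation p passes, so that difference is not settled. These 5 differences were chosen after the values were seen. They do not set ribosomal protein genes apart from all essential complexes. The chaperonin TRiC and the RNA polymerase II subunits, among the lists added later, had medians of -0.53 and -0.44. Ribosomal protein genes were not tested against them.

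**Figure D3:**
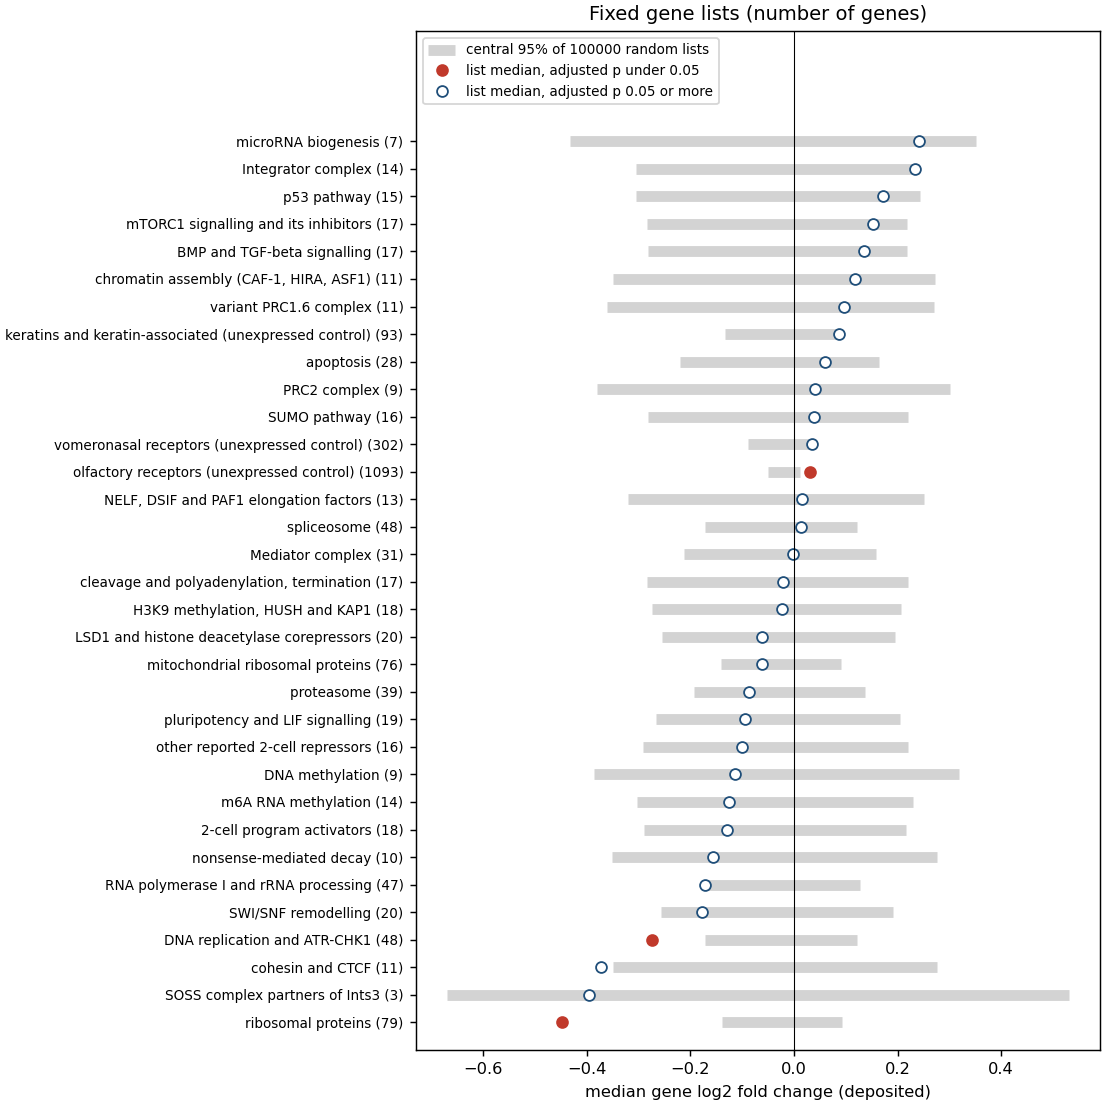
Median log2 fold change of the genes of each of the 33 fixed lists (points, number of genes in brackets), with the central 95% of 100000 random lists of the same size (grey bars). The filled points are the 3 lists with an adjusted p under 0.05, ribosomal proteins at -0.45, DNA replication at -0.27 and olfactory receptors at 0.031.

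Lists of known or reported regulators of the 2-cell state did not pass. At 3.84 sorted cells per library guide, this does not exclude an effect. The median was 0.096 for 11 genes of the variant Polycomb complex PRC1.6, 0.12 for 11 chromatin assembly genes, -0.024 for 18 genes of H3K9 methylation, HUSH and KAP1, 0.038 for 16 SUMO pathway genes, -0.061 for 20 genes of LSD1 and histone deacetylase complexes and -0.10 for 16 other reported repressors, with adjusted permutation p-values of 0.693, 0.693, 0.987, 0.802, 0.815 and 0.752. Rnf2, the ubiquitin ligase of Polycomb complex 1, on chromosome 1 from 151469398 to 151500991, had a log2 fold change of 1.10 in the authors' deposited table, with 4 of 6 guides up and rank 29. Its enrichment p was 0.00165 at a false discovery rate of 0.827 in the authors' deposited table, and 0.0182 adjusted over the list alone, which 1 of the 11 members passed. Mbd3, of the NuRD complex, had a value of 0.69 and Eif1a one of 0.78 in the authors' deposited table, each with 5 of 6 guides up and unadjusted p-values of 0.0234 and 0.0418. The 18 activators of the 2-cell program had a median of -0.13 (adjusted permutation p = 0.693). Their transcription factor Dux, chosen after its values were seen, had a log2 fold change of -1.41 with 3 of 3 guides down in the authors' deposited table. Its depletion p of 0.00419 in the authors' deposited table came to 0.0753 adjusted over the list alone. Dux has several near-identical copies in the genome, so its value is uncertain.

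Olfactory receptor genes had a permutation p of 0.0012 and an adjusted p of 0.0132 against random lists drawn from all genes, and 582 of 1093 lay above 0. Their median differed from that of the non-targeting guides by 0.013 (bootstrap 95% interval -0.033 to 0.063), and their mean of 0.0055 from the -0.040 of these guides by 0.045 (-0.0072 to 0.10). Both intervals span 0, so a rise over guides with no target was not detected. The comparison sets gene values, mostly of 6 guides, against single guides with a standard deviation of 0.770. It therefore cannot exclude a rise. An unadjusted enrichment p under 0.05 was held by 67 of them, or 6.13%, against 4.96% of other genes in the authors' deposited table (two-sided Fisher's exact p = 0.0873). A depletion p under 0.05 was held by 25, or 2.29%, against 5.23% in the authors' deposited table (Fisher's exact p = 2.55e-06). Both Fisher tests and the comparison with non-targeting guides were chosen after the values were seen. The medians of the other silent families were 0.034 for 302 vomeronasal receptor genes and 0.086 for 93 keratin genes, with adjusted permutation p-values of 0.289 and 0.275. Their best-ranked members were Vmn2r111 at 1.29 and Krtap2-4 at 2.84, the second with a single guide, in the authors' deposited table.

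None of the remaining 16 lists passed. Medians above 0.1 were found for microRNA biogenesis (0.24), the p53 pathway (0.17), mTORC1 signalling (0.15) and BMP and TGF-beta signalling (0.13), with adjusted permutation p-values of 0.495, 0.495, 0.495 and 0.514. Atm, a DNA damage kinase, had a value of 0.84 and Smad7, an inhibitor of TGF-beta signalling, one of 0.39 in the authors' deposited table, with unadjusted p-values of 0.0333 and 0.0331. The lowest medians were those of 3 partners of Ints3 in the SOSS complex (-0.40), cohesin and CTCF (-0.37), SWI/SNF remodelling (-0.18) and nonsense-mediated decay (-0.16), with adjusted permutation p-values of 0.495, 0.233, 0.495 and 0.693. Stag1, a cohesin subunit, had a value of -0.026 and Arid1a, a SWI/SNF subunit, one of 0.44 in the authors' deposited table, with unadjusted enrichment p-values of 0.00739 and 0.0134. The medians of the m6A methylation (-0.12), DNA methylation (-0.11), pluripotency (-0.094), apoptosis (0.060), PRC2 (0.041), elongation factor (0.015), termination (-0.022) and Mediator (-0.0018) lists had adjusted permutation p-values of 0.693, 0.763, 0.752, 0.693, 0.815, 0.888, 0.987 and 0.898. Cdk8, the Mediator kinase, chosen after its values were seen, was the 1 Mediator gene past 0.05 adjusted over the list alone (depletion, 0.0208), with 2 guides up, 2 down and a log2 fold change of -0.14 in the authors' deposited table. The best-ranked members of other lists were Esrrb at 0.62, Zc3h13 at 0.65, Snrpc at 0.67, Mrpl19 at 0.97 and Psmb10 at 1.10 in the authors' deposited table. Bad at -0.33, Noc2l at -0.14 and Nprl2 at -0.55 in the authors' deposited table had unadjusted enrichment p-values of 0.0234, 0.00179 and 0.00774, although more of their guides were down than up.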

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

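The reading with the direction turned, the genes-only adjustment, the median depletion rank and Integrator without Ints7 were chosen after the data were seen, and the other alternatives before. No gene was enriched at a threshold of 0.01 or 0.25, among genes with at least 4 guides, with Benjamini-Hochberg values recomputed over all entries or over genes only, with an absolute log2 fold change of at least 1, or with at least 2 guides past the guide threshold. With the direction turned, 1 gene was enriched and 0 were depleted. The count of 1 depleted gene held under these alternatives, except that with an absolute log2 fold change of at least 1 it was 0, since Gm10413 had -0.99. Ints7 moved from rank 157 to 7877 when entries were ranked by log2 fold change, and stood at 155 and 154 among entries with at least 4 guides and with at least 2 guides past the threshold. Of 33 lists, 3 passed with the mean, with at least 4 guides and without the most extreme member, and 2 by either median rank, where the replication list was lost. With receptor and keratin genes left out of the background or as the background, 2 of 30 lists passed, since the olfactory list was not tested there. Of 226 values of single lists under the alternatives, 188 kept their direction and side of the threshold. The replication list lost its call by median enrichment rank (11877.5) and median depletion rank (7218). In 36 values of 16 lists the sign or the side of the random lists' centre reversed, 0 of them past the threshold under either setting. With the mean these were elongation factors (-0.023), Mediator (-0.11), PRC2 (-0.031), spliceosome (-0.014), microRNA biogenesis (-0.040) and vomeronasal receptors (-0.018). By median enrichment rank they were elongation factors (12059), termination (9687), Mediator (11165), H3K9 methylation (9467.5), pluripotency (10229), spliceosome (11397.5), cohesin (8527) and vomeronasal receptors (11678.5). By median depletion rank they were elongation factors (8526), termination (11817), Mediator (8617), H3K9 methylation (12544.5), LSD1 (11169), PRC2 (5982), 2-cell activators (11821), other 2-cell repressors (13877.5), the p53 pathway (10990) and keratins (10262). Without receptor and keratin genes in the background they were termination (-0.022) and H3K9 methylation (-0.024), and with these genes as background elongation factors (0.015), Mediator (-0.0018), spliceosome (0.014) and PRC1.6 (-0.020). PRC1.6 also had -0.020 among genes with at least 4 guides and without its most extreme member, and without theirs termination had 0.012, Mediator 0.0067, H3K9 methylation -0.0083 and LSD1 -0.019. The cause of these changes was not tested. No paired analysis was possible because the table holds 1 comparison per entry and no columns per library. For the same reason leaving out each replicate, the replicate block, other normalizations, the low-count filter, the removal of guides at 0 and other splits of the libraries were not run. Depth per library is unknown. Simulated lists held only genes with 5 or 6 guides, were set against fewer random lists, and were called at an unadjusted permutation p under 0.05. A shift of -0.2 was found in 14% of 14-gene, 38% of 20-gene and 98% of 79-gene lists, and upward shifts were not simulated. Shifts of that size were thus mostly out of reach for lists as small as Integrator, and adjustment over 33 lists is stricter.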

Other observations

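Chosen only after the results were seen were the 16 further lists, the single genes named, the count of receptor genes among the first ranks, the spread of control genes, the chromosome medians and the tests of scatter, of receptor gene clusters and of direction. Of the 16 further lists, none passed an adjusted permutation p of 0.05. Lowest were the 8 genes of the chaperonin TRiC, which folds actin and tubulin, with a median of -0.53, and the 12 subunits of RNA polymerase II, with a median of -0.44 and all 12 below 0. Their permutation p-values were 0.00627 and 0.00549, and both had an adjusted p of 0.0502 over 16 lists. Medians were -0.27 for RNA polymerase II tail and cap factors, -0.26 for the anaphase-promoting complex, -0.26 for aminoacyl-tRNA synthetases, -0.19 for mitochondrial protein import and -0.19 for the V-ATPase, with adjusted permutation p-values of 0.241, 0.241, 0.194, 0.338 and 0.293. The TIP60-EP400 complex, the Wnt pathway, JAK-STAT, GPI anchor synthesis, TFIID, translation initiation, respiratory complex I, zinc finger genes and defensins had medians of 0.0062, 0.064, -0.063, -0.095, -0.035, -0.096, 0.021, -0.019 and -0.035, with adjusted permutation p-values from 0.61 to 0.956.

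Some members of lists whose medians did not pass had low unadjusted p-values. Epc1, a partner of Dmap1 in the TIP60 complex, had a log2 fold change of 1.16 with 6 of 6 guides up and an unadjusted p of 0.002 in the authors' deposited table, at a false discovery rate of 0.867. Of the 16 members of the TIP60-EP400 list, 8 lay above 0 and 8 below. Its member Ruvbl1 had a value of -1.35 with 4 of 6 guides down and 1 up in the authors' deposited table (unadjusted depletion p = 0.0405). Jak2, a kinase of cytokine receptors, had a value of -2.24 with 6 of 6 guides down, rank 9 for depletion and a false discovery rate of 0.482 in the authors' deposited table. Of the first 30 genes by enrichment rank in the authors' deposited table, 6 were olfactory receptor genes, or 20%, against 5.36% of all genes (hypergeometric p = 0.0046).

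Receptor and keratin genes with 6 guides had a standard deviation of 0.451 across 1145 genes in the authors' deposited table, close to the 0.456 of all 16270 genes with 6 guides. Medians of 6 non-targeting guides drawn at random had one of 0.297, and how the gene values were combined from guides is not given in the sources used here.

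Ribosomal protein genes lay low. Scatter of scarce guides stays open: 23.7% of the guides were up (bootstrap 95% interval 20.1 to 27.6) against 37.4% over all genes, but the non-targeting guides also scattered further down than up, with 95% of them between -1.65 and 1.34, and guide abundance was not analysed here. Cutting at named pseudogene copies cannot be told apart, since 59 genes with a named pseudogene and 20 without differed by -0.033 (95% interval -0.30 to 0.30, permutation p = 0.899) and the naming of pseudogenes is incomplete. The 20 without one also lay low (permutation p = 0.00096), and a biological difference between sorted and total cells stays open, untested.

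Genes of chromosome 9 lay high, with a median of 0.060 over 1167 genes against -0.049 to 0.0097 for random gene sets, the 1 chromosome of 21 past 0.05 (adjusted permutation p = 0.00021). Without receptor gene clusters the median was 0.055, with a permutation p of 1e-05, the smallest possible, which argues against these clusters as the whole cause. Few essential genes on the chromosome stays open as an explanation, since leaving out 6 lists of essential genes (permutation p = 1e-05) removed 17 of the 1167 genes, too few to change the median, and the lists hold 1.46% of the chromosome's genes and 1.65% of all genes. In 11 of 13 intervals of 10 Mb the median lay above that of all genes, and chromosome 11 with a low median of -0.055 and chromosome 19 with a high one of 0.034 had an adjusted permutation p of 0.0512 each. No biological explanation was tested, and a change in chromosome number in part of the cells was not tested either.

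The direction of the table was tested on its own lists. If positive values mean more guides in MERVL-positive cells, genes of reported repressors could lie above activators of the 2-cell program. The 92 repressors lay above the 18 activators by 0.13 on the log2 scale (95% interval -0.19 to 0.32, permutation p = 0.294). The directions cannot be told apart by this test, since the interval spans 0.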
